A study of Mus musculus with 16 samples.

How the data were processed

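The measurements are single-cell RNA sequencing of mouse cerebellum from a line in which the Y chromosome lacks the testis-determining gene Sry and an Sry transgene on an autosome gives testes, so that XX and XY animals occur with either gonad. The 16 libraries fall into 8 groups of 2 libraries each, by stage (E16.5 or E18.5), sex chromosomes (XX or XY) and gonads (ovaries or testes), with 8 libraries at each level of each factor. The replicates carry the numbers 2 and 3 in every group. The labels do not say whether the 2 libraries of a group come from separate animals, nor give a litter, a day or a sequencing batch, so each p-value here measures the spread between libraries.

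The deposited matrices hold counts: whole numbers of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. Per the labels, the authors made them with Cell Ranger 5.0.1 against the mouse genome build mm10, from droplet libraries prepared one per sample. The header lines of the matrix files give software version 3.0.2, and the files cannot settle which version holds. The barcodes are already limited to called cells, so the free RNA of empty droplets cannot be measured. The 16 files list 32285 genes, and 32235 of these gene IDs matched GENCODE vM21 (build GRCm38), from which chromosomes and positions were taken.

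Each library held 8063 to 14309 barcodes, and the cells analysed in the end held 81414759 to 147334012 UMIs per library. Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which left 7784 to 12801 per library and 154112 in all. The median depth of all barcodes, before this filter, was 8854 to 11719 UMIs per library. Scrublet scores marked doublets: the cells with the highest scores were left out after clustering, 0.8% of cells per 1000 kept barcodes, which came to 6.23 to 10.24% per library and left 141997 cells (7299 to 11490 per library). Kept cells of all libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2, without batch integration, on the logarithm of counts per 10000, 2000 variable genes (sex chromosome, mitochondrial, ribosomal protein and hemoglobin genes left out), 30 principal components, 15 nearest neighbours and Leiden resolution 1.5. This gave 63 clusters. A cluster took the name of the marker list, fixed before the data were examined, that scored highest in it with at least 3 detected markers. The thresholds of this naming (minimum score 0.5, margin 0.1 over the next list, doublets at most 50%) were set after the clusters were seen. A median depth of at least 0.4 of the library median was asked only of clusters with under 3 markers of their list among the 10 leading genes. Erythroid-like clusters, at 0.267 to 0.388, were named for that reason. Clusters whose leading genes held more markers of another list, or granulocyte genes, stayed unnamed. With these rules 49 clusters with 136067 cells were named. A further 7 clusters with 834 cells held mostly doublets, and 7 clusters with 5096 cells missed another rule. Those stayed unnamed but count in the sums over all cells and in the denominators of shares. Class names end in "-like" since they rest on markers alone. Several classes are led by different clusters at the 2 stages, so that a stage difference within a class holds both change within cells and change of cells.

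For each library, counts were summed over all analysed cells and over each class with at least 20 cells in every library. This left 9 classes, of which erythroid-like cells had the smallest sum and Purkinje-like cells the largest. Genes passed the filter of edgeR 4.0.16 (filterByExpr over the 8 groups), which kept 19830 genes in all cells and 7553 to 14914 per class. An additive quasi-likelihood model with terms for stage, chromosomes and gonads was fitted per population with TMM factors. Each contrast was tested two-sided and adjusted by Benjamini-Hochberg over the genes of that population, and a gene is called at an adjusted p under 0.05. The interactions of gonads with chromosomes and of gonads with stage were each fitted in a model of their own, from which the gonads effect within a stage was also taken. Differences are testes minus ovaries, XY minus XX and E18.5 minus E16.5, on the log2 scale with their standard error (SE). Group levels are means of CPM (the count of a gene per 1e6 counts of its library) with the standard deviation over libraries, scaled by the TMM factors except in the check of labels, which uses library totals. DESeq2 1.42.0 was run with the same design. Where its independent filtering gave no adjusted p, the gene counts as not called.

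Class shares are percentages of analysed cells. They were compared by an exact two-sided permutation test of the difference in means, permuting the labels within the 4 combinations of the other factors. This gives 1296 arrangements and a smallest possible p of 0.0015, adjusted over the 16 classes of a contrast.

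Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 tested genes, adjusted over all 213 list-and-population pairs of a contrast. Camera with an estimated correlation and fry were run beside it. The 25 lists tested cover the X-inactivation centre and escape genes, an X segment reported on the Y of some colonies of this line, steroid receptors and metabolism, androgen response, sonic hedgehog targets, S phase, G2 and M phase, Notch and progenitor genes, gliogenesis, motile cilia, polycomb repressive complex 2, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, synapse, immediate early and dissociation stress genes, cytosolic ribosomal proteins, mitochondrially encoded genes, hemoglobin, choroid plexus, microglia, blood vessel, meningeal fibroblast, hindbrain Hox and midbrain genes. The list of Y-linked genes had too few tested members for camera and is given gene by gene.

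Named genes follow a rule fixed before the data were examined: the genes of the label check; in all cells the 10 highest and 10 lowest called autosomal genes with a mean of at least 10 CPM and the same sign in the 4 combinations of the other factors; per class the 3 smallest p-values per direction among called genes; the called members of the sex chromosome lists; up to 2 members per direction of each list in the population with its smallest adjusted p; and the 5 smallest p-values of each interaction. Some genes that were selected are not reported here. Genes named outside this rule are said to be chosen after their values were seen.

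Alternatives fixed beforehand were DESeq2 size factors in edgeR, library totals, no filter on low counts, the DESeq2 test, the replicate number as an additive term or as a term within each stage, a minimum of 2000 UMIs, a maximum of 5% mitochondrial UMIs, doublets kept, Leiden resolution 0.8, an estimated correlation for lists, logit shares, and leaving out each of the 16 libraries in turn with the tested genes kept as in the full set. With 1 library left out a group holds a single library, which is assumed to vary like the other groups. Leaving out both libraries of E18.5 XX ovaries together was added after the results were seen. Replicate numbers do not pair the libraries across groups: over 28 pairs of groups the correlation of the within-group differences had a median of -0.038 and ranged from -0.616 to 0.552. The models were tested on simulated data with known changes. Calls recovered 36 to 81% of genes changed 1.5-fold and 78 to 95% of genes changed 2-fold per population, with 3.61 to 6.88% false calls. Each gene was drawn on its own there, without a stage difference and without a library that deviated in many genes at once. The real gonads counts rested on single libraries, so these rates need not hold for the real calls. The share test passed its unadjusted threshold in 4.0% of simulations without a change and in 96.5% with a 1.5-fold change. These simulations set a relative standard deviation of 0.2 between libraries. Some real classes spread more, such as choroid plexus-like cells at 1.77 ± 2.17% in E18.5 XX ovaries (SD, n = 2). The 96.5% does not hold for such classes, nor after adjustment over classes. Earlier looks at the real data came before this simulation. R 4.3.3 and python 3.11.15 with scipy 1.17.1 were used.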

Results

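Transcripts of single cells were counted in cerebellum from 16 mouse libraries, 2 libraries for each combination of embryonic day (E16.5 or E18.5), sex chromosomes (XX or XY) and gonads (ovaries or testes). In this mouse line the testis-determining gene is carried apart from the Y chromosome, so that the gonad does not follow from the sex chromosomes and a difference by gonads, which includes the hormones the gonads make, was set apart from a difference by chromosomes. The title of the series names androgen activity in the embryonic hindbrain. Each library held 8063 to 14309 barcodes, of which 7299 to 11490 entered the comparisons as cells, with 81414759 to 147334012 UMIs over these cells. The cells fell into 16 classes by marker genes. Granule progenitor-like, granule neuron-like, Purkinje-like, radial glia and astroglia-like and GABAergic interneuron lineage-like cells were the most frequent.

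The chromosome labels were checked with Y-linked genes and with Xist. Xist, the noncoding RNA that coats the inactive X chromosome, reached 1069 to 1242 CPM in the 4 XX groups and 0.0705 to 0.124 CPM in the 4 XY groups. Ddx3y, a Y-linked RNA helicase gene, lay at 56.0 to 66.8 CPM in the XY groups and had no count in any of the 8 XX libraries, where 3 counts over the group would be 0.00326 CPM. Eif2s3y, Kdm5d and Uty, further Y-linked genes, averaged 50.2 ± 5.32, 21.8 ± 1.98 and 21.5 ± 1.24 CPM (SD, n = 8) in XY libraries and 0.00119, 0.0192 and 0.0118 CPM in XX libraries. All 16 libraries matched their chromosome label. Sry itself gave 1 count in all libraries together, in a library with testes, so the gonad label cannot be checked with these genes.

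**Figure D1:**
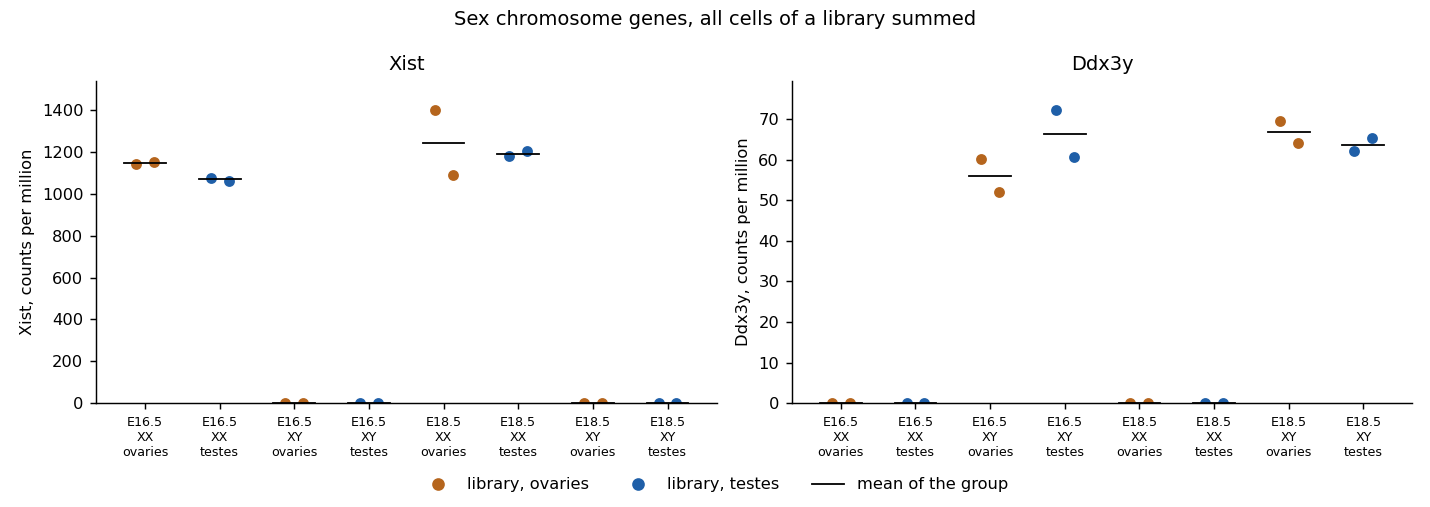
CPM of Xist and of Ddx3y in each library, with all analysed cells summed, for the 8 groups of 2 libraries. Points are libraries coloured by gonads and lines are group means. Xist lies at 1069 to 1242 CPM on average in XX groups, and Ddx3y at 56.0 to 66.8 CPM in XY groups.

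The comparison of stages asks what differed between the libraries of E16.5 and E18.5, the span in which granule cells multiply in the external layer. The labels give no day or batch of processing, so a difference of processing between the stages cannot be told apart from stage. Granule neuron-like cells rose from 9.31 ± 1.52 to 22.3 ± 2.41% of cells (SD, n = 8, exact permutation test, adjusted p = 0.00353), and granule progenitor-like cells from 12.7 ± 2.06 to 22.6 ± 2.34% with the same adjusted p. Unipolar brush cell-like cells, another product of the rhombic lip, rose from 3.58 ± 0.744 to 7.95 ± 0.891%. Purkinje-like cells, the output neurons of the cerebellar cortex, fell from 20.1 ± 3.29 to 6.93 ± 1.81%. GABAergic interneuron lineage-like cells fell from 13.9 ± 0.888 to 8.15 ± 1.08% and glutamatergic nuclear neuron-like cells from 3.49 ± 0.982 to 0.715 ± 0.562%. Radial glia and astroglia-like cells rose from 11.5 ± 2.18 to 15.1 ± 2.58% (exact permutation test, adjusted p = 0.00741), oligodendrocyte lineage-like cells from 0.405 to 0.925% and ependymal-like cells from 0.00259 to 0.113%. Outside the neural lineages, erythroid-like, meningeal fibroblast-like and choroid plexus-like cells fell, the last from 4.45 ± 2.06 to 2.28 ± 1.16%. This last call, a difference of -2.172 percentage points, was lost at Leiden resolution 0.8 (-1.377) and without E16.5 XX ovaries replicate 3, E18.5 XX ovaries replicate 2 or E18.5 XY testes replicate 2 (-2.07, -1.788 and -2.232), and that of fibroblast-like cells without E18.5 XY testes replicate 2 (-2.814 in place of -3.234). In all, 12 of 16 shares changed. Shares add up to a fixed total, so a lower share need not mean fewer cells.

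**Figure D2:**
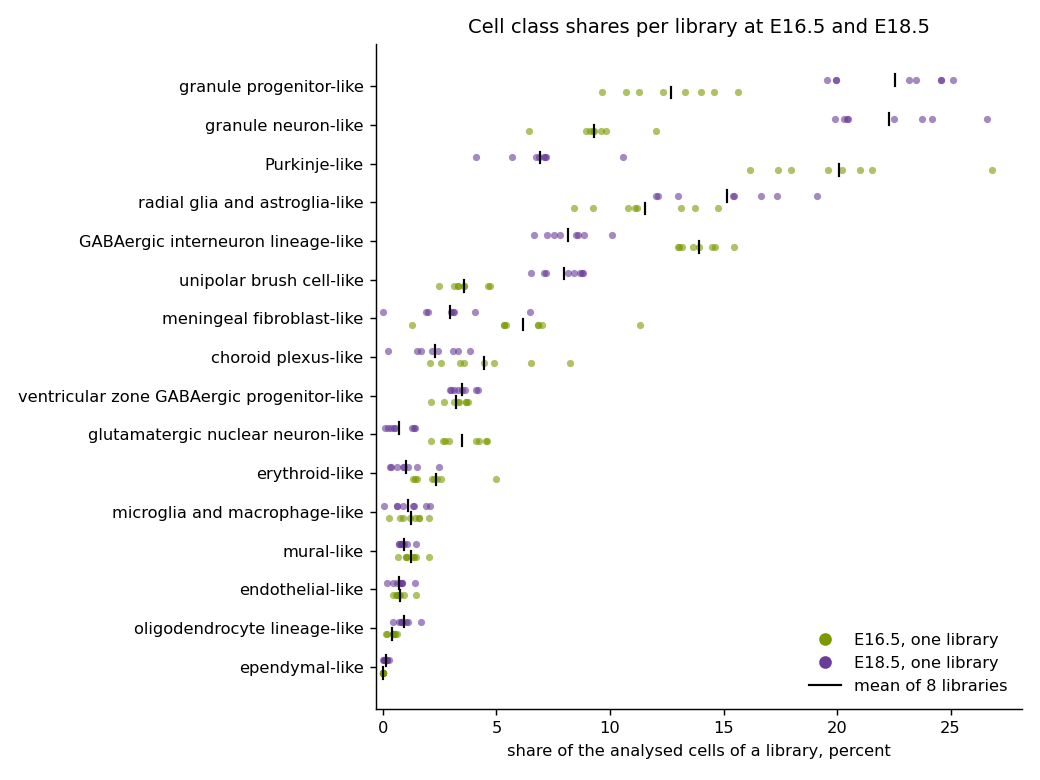
Share of each cell class among the analysed cells of a library, in percent, at E16.5 and at E18.5. Points are single libraries and bars are means of 8 libraries. Granule neuron-like and granule progenitor-like cells have higher shares at E18.5, at 22.3 and 22.6%, and Purkinje-like cells have a lower share there, at 6.93%.

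With all cells summed, among called autosomal genes with a mean of at least 10 CPM and the same sign in the 4 combinations of the other factors, those that rose most from E16.5 to E18.5 were Tac2, which encodes a tachykinin precursor, and histone genes. Tac2 (chromosome 10, 127724478 to 127731768) went from 0.909 ± 0.325 to 19.8 ± 10.6 CPM (SD, n = 8), a log2 difference of 4.45 ± 0.276 (SE, edgeR adjusted p = 3.56e-08). Of the 10 highest named genes, 8 encode histones: the linker histone genes Hist1h1b, Hist1h1a and Hist1h1e rose by 2.97, 2.56 and 2.40, and the core histone genes Hist1h2ab, Hist1h2ap, Hist1h4h, Hist1h4d and Hist2h2ac by 2.33 to 3.37. Most histone transcripts lack the poly(A) tail that this kind of library captures. Gm42418, a gene model that overlaps ribosomal RNA sequence, rose by 2.27 from 198 ± 25.7 to 956 ± 138 CPM. The lowest named genes were the globin genes Hbb-y, Hbb-bt, Hba-a2, Hbb-bs and Hba-a1, which fell by 1.85 to 3.02. Slc16a10, an amino acid transporter gene, fell by 1.85, Meis2, a transcription factor gene of nuclear neurons, by 1.85, the receptor gene Notch2 by 1.81, the matrix gene Lum by 1.71 and Tafa2 by 1.58. The fall of globin and Lum moved with the lower shares of erythroid-like and meningeal fibroblast-like cells. In all, 6131 genes rose and 5550 fell among 19830 tested. The call of Hbb-y was lost in 9 of its alternative settings.

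Within classes, the genes named here are those with the smallest p-values. In Purkinje-like cells Itpka, a kinase gene of dendritic spines, rose by 3.45 ± 0.155 (SE) from 2.05 to 22.5 CPM, and Rasl11b by 1.34, while Lrrc8a, Runx1t1 and the histone demethylase gene Kdm6b fell by 1.15, 1.18 and 0.91. In GABAergic interneuron lineage-like cells Nfix, a nuclear factor I gene, rose by 1.86, while Bcl11a, Runx1t1 and Inpp4a fell by 1.68, 1.93 and 1.13. Radial glia and astroglia-like cells gained Aqp4, the astrocyte water channel gene, by 2.38 ± 0.084 (SE, edgeR adjusted p = 6.63e-13) from 18.8 ± 5.16 to 97.3 ± 19.1 CPM (SD, n = 8), and lost Msi1, a progenitor RNA-binding protein gene, by 0.97. Dpysl2, which acts in axon growth, fell by 0.96 in granule neuron-like, 0.92 in granule progenitor-like and 0.88 in unipolar brush cell-like cells. There Sox11 and mt-Cytb fell by 1.01 and 0.66, while Patj and Dclk3 rose by 1.46 and 2.17. Ventricular zone GABAergic progenitor-like cells lost Pdpn, the Notch ligand gene Jag1 and Spry2 by 1.25, 0.89 and 1.45. Mural-like cells gained Itih5 and G0s2 by 2.05 and 1.39 and lost Alyref, Pfn1 and Actb by 0.98, 0.50 and 0.57.

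Some stage differences ran through many classes at once. Gm42418 rose by 2.13 to 2.89 in all classes where it is named, Lars2 by 1.62 to 1.82 in granule neuron-like, granule progenitor-like and radial glia and astroglia-like cells, and Hist1h1e by 2.04 in granule neuron-like cells. Hist1h1b rose by 2.16 in radial glia and astroglia-like, 2.71 in ventricular zone GABAergic progenitor-like and 3.23 in erythroid-like cells, where Hist1h4d rose by 3.55, and Hist1h2ab rose by 2.65 and 3.17 in both progenitor-like classes. Actb, the cytoskeletal actin gene, fell by 0.78 in granule neuron-like and by 0.77 in radial glia and astroglia-like cells. Rimklb fell by 0.70 in granule neuron-like cells, Ppp4c and Btg1 by 0.62 and 0.66 in granule progenitor-like cells, and Wtap by 0.71 in radial glia and astroglia-like cells. In erythroid-like cells the neuronal genes Foxp2, Dpysl2 and Sox4 fell by 2.88, 1.14 and 1.37. These genes are not known from red blood cells, and Purkinje-like cells, which express Foxp2, had a lower share at E18.5. Over the 9 classes, 25013 gene-and-class pairs rose and 23078 fell.

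Gene lists passed camera for stage with a preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.153 to 0.95). In ventricular zone GABAergic progenitor-like cells all 49 tested G2 and M phase genes rose, with a median of 0.599, and 35 of 42 S phase genes. The make-up of this class moved too: the cluster with most of its cells at E16.5 (72.8%) gave way at E18.5 to another (50.2%) with Hist1h1b, Top2a and Pbk among its markers. In mural-like cells 45 of 48 G2 and M phase genes fell, with a median of -1.62, Kif2c and Tmpo by 2.40 and 0.86, and Cbx5 stayed at 0.06 (adjusted p = 0.77). S phase genes fell there in 30 of 40, with Tyms and Nasp at -1.84 and -0.56 and with Ubr7 at 0.09, not called. Sonic hedgehog targets, the mitogen response of granule progenitors, rose in 11 of 16 in all cells, with Gli2 at 1.23 and Ccnd1 at 0.89. Cdon of this list fell by 0.32, a call lost in 6 of 16 fits with a library left out, and Sfrp1 lay at -0.33 without a call. Gliogenesis genes rose in 17 of 22 in radial glia and astroglia-like cells, Apoe by 1.58, while Nfia and Nfib fell by 0.46 and 0.15. Cholesterol synthesis genes rose there in 22 of 23, Cyp51 by 0.72 and Mvk by 0.46, and Insig1 lay at -0.04. Notch and progenitor genes fell in 15 of 20 in granule progenitor-like cells, with Jag1 at -1.47 and Notch2 at -1.17, while Dll3 and Hey1 rose by 1.01 and 0.26. Synapse genes rose in 21 of 32 in Purkinje-like cells, Cntn1 by 1.36 and Syn2 by 0.82, while Grin2b and Gabra2 fell by 0.95 and 0.77. Glycolysis and hypoxia genes rose in 19 of 26 there, Ldha by 0.62 and Pfkp by 0.68, with Ankrd37 down by 0.14 and Gapdh at -0.07.

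Other lists moved with stage in fewer populations. Oxidative phosphorylation genes fell in 48 of 72 in all cells, Atp5o by 0.33 and Atp5c1 by 0.35, while Sdha and Ndufa3 rose by 0.09 and 0.29, calls lost in 2 and 6 of 16 fits with a library left out. Ribosomal protein genes rose in 68 of 77 in erythroid-like cells, Rps27 and Rps29 by 1.16 and 1.32. Of 13 mitochondrially encoded genes in unipolar brush cell-like cells 8 fell, mt-Co3 by 0.61, and 3 rose, with mt-Atp8 at 1.25 and mt-Nd3 at 0.54. All 6 hemoglobin genes fell in granule progenitor-like cells, Hba-a2 by 2.41 and Hbb-bs by 2.35. Of 5 choroid plexus genes in unipolar brush cell-like cells 3 rose, among them Prlr and Folr1 by 1.33 and 1.17, while Ttr, the most abundant of them in choroid plexus, lay at -0.22 (adjusted p = 0.569). Blood vessel genes rose in 3 of 5 in mural-like cells, Pdgfrb by 0.63 and Vtn by 0.61. Motile cilium genes fell in 18 of 28 in all cells, Foxj1 by 1.06 and Dynlrb2 by 1.16, while Tmem212 and Ccdc153, made by ependymal cells, rose from 0.00114 to 0.830 CPM and from 0.0757 to 0.858 CPM. Polycomb genes fell in 8 of 13 in Purkinje-like cells, Kdm6b by 0.91 and Rbbp4 by 0.60, with Aebp2 and Rbbp7 up by 0.38 and 0.23. In all, 60 of 213 list-and-population pairs passed camera, 36 up and 24 down. With an estimated correlation 0 of them held, at an adjusted p of 0.153 to 0.95, while fry called 56 of the 60. Adjusted over the list alone, the counts named here are the same or higher, such as 46 of 48 for G2 and M phase and 35 of 40 for S phase genes in mural-like cells.

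The comparison of chromosomes asks which genes differ between XX and XY cerebellum when both gonads are present in each. The differences lay almost wholly on the sex chromosomes. Xist (chromosome X, 103460366 to 103483254) was at 1153 ± 101 CPM in XX and 0.0903 ± 0.0381 CPM in XY libraries (SD, n = 8, edgeR adjusted p = 5.37e-18), and its antisense gene Tsix at 37.8 ± 22.2 against 0.0803 ± 0.0270 CPM. The other way, Ddx3y, Eif2s3y, Kdm5d and Uty were at 63.7, 50.5, 21.9 and 21.7 CPM in XY libraries, next to the Y-linked Gm29650, Uba1y and Gm28587 at 0.859, 0.0680 and 0.0615 CPM, which were named after their values were seen. Genes that escape X inactivation, and so are expressed from both X chromosomes, were lower in XY: the histone demethylase genes Kdm6a and Kdm5c by -0.57 ± 0.066 and -0.42 ± 0.035 (SE), the translation factor gene Eif2s3x by -0.55 ± 0.047, 5530601H04Rik by -0.44, Jpx by -0.43 and Pbdc1 by -0.31. Among the 618 other X-linked genes tested, edgeR called 0, with a median difference of 0.018.

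The escape genes held this direction across classes. Eif2s3x was lower in XY by 0.47 to 0.56 on the log2 scale in 7 classes, with a change of -0.56 in GABAergic interneuron lineage-like and -0.47 in granule progenitor-like cells. Kdm6a ranged from -0.67 in ventricular zone GABAergic progenitor-like to -0.40 in Purkinje-like cells, and Jpx from -0.68 to -0.51 in the classes where it was called. Of the X-inactivation centre and escape list, 8 of 11 genes were lower in radial glia and astroglia-like cells and 10 adjusted over the list alone. The list passed camera in all 10 populations also with an estimated correlation (adjusted p = 2.18e-11 in radial glia and astroglia-like cells and 1.01e-05 in erythroid-like cells). In unipolar brush cell-like cells the call of Kdm6a (-0.57) was lost in 12 of 16 fits with a library left out, as was that of 5530601H04Rik (-0.40) in ventricular zone GABAergic progenitor-like cells in 13 of 16 and that of Pbdc1 (-0.30) in granule neuron-like cells in 10 of 16.

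Few autosomal genes were called by chromosomes, and these were named after their values were seen. Crlf2, a cytokine receptor gene on chromosome 5, was lower in XY by -0.58 ± 0.087 (SE) in granule neuron-like cells (5.82 ± 0.825 against 8.66 ± 0.746 CPM, n = 8, edgeR adjusted p = 0.00267), by -0.53 in granule progenitor-like and by -0.40 in GABAergic interneuron lineage-like cells. In radial glia and astroglia-like cells Col5a2, a collagen gene, lay at -0.38 and Mxra8 at -0.46. Gata3, a midbrain and brainstem factor gene, lay at 1.54 ± 2.83 against 0.0406 ± 0.0566 CPM in GABAergic interneuron lineage-like cells, a difference carried by few libraries. In all, 15 genes were called with all cells summed, 7 higher and 8 lower in XY, and 95 gene-and-class pairs, 39 higher and 56 lower.

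Beyond the sex chromosome genes, 25 list-and-population pairs passed camera for chromosomes, and none held with an estimated correlation (adjusted p = 0.342 to 0.982). No member of these lists was called. In erythroid-like cells G2 and M phase genes had a median of -0.27, with Cdca8 at -0.42, Anp32e at -0.24, Dlgap5 at 0.45 and Kif23 at 0.13. S phase genes there had a median of -0.233, with Mcm6 at -0.54, Chaf1b at -0.76, Wdr76 at 0.53 and Slbp at 0.12. Ribosomal protein genes had a median of -0.109, with Rps3 at -0.20, Rpl10 at -0.19, Rpl38 at 0.03 and Rps27 at 0.02. Stress genes had a median of 0.24, with Klf6 at 0.77, Hspa8 at -0.12 and Hspe1 at -0.05, and 2 of 16 were higher when adjusted over the list alone. Cholesterol synthesis genes had a median of 0.155, with Cyp51 at 0.26 and Fdps at -0.05. Glycolysis genes in granule neuron-like cells had a median of 0.092, with Ndrg1 at 0.36, Pdk1 at 0.25, Adm at -0.33 and Ddit4 at -0.03. In unipolar brush cell-like cells synapse genes had a median of 0.109, with Syt1 at 0.17, Nefm at -0.04 and Nefl at -0.02, and mitochondrially encoded genes one of 0.09, with mt-Nd5 at 0.22 and mt-Nd6 at 0.47. Oxidative phosphorylation genes in GABAergic interneuron lineage-like cells had a median of 0.055, with Ndufb3 at 0.12, Ndufb11 at 0.09, Uqcrc1 at -0.05 and Uqcrfs1 at -0.02. No class share differed by chromosomes: 0 of 16 passed the exact permutation test, with 1 at an unadjusted p under 0.05, unipolar brush cell-like cells with 5.35 ± 2.56% in XY and 6.18 ± 2.30% in XX (p = 0.0340, adjusted p = 0.543). Leaving out E16.5 XY testes replicate 2 raised the count of list pairs from 35 to 55.

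The comparison of gonads asks what differs between cerebella of animals with testes and with ovaries, whatever their chromosomes. Mid1 and Ptgds passed the test in 5 and 6 classes, both higher with testes. Mid1, an X-linked gene for a microtubule-associated ubiquitin ligase (chromosome X, 169685199 to 170005736), was at 29.0 ± 4.45 CPM with testes and 18.7 ± 1.59 CPM with ovaries in Purkinje-like cells (SD, n = 8), a difference of 0.61 ± 0.082 (SE, edgeR adjusted p = 0.00372). It was higher by 0.77 ± 0.105 in granule neuron-like, 0.87 ± 0.146 in unipolar brush cell-like, 0.79 ± 0.123 in granule progenitor-like and 0.82 ± 0.130 in radial glia and astroglia-like cells, each in all 4 combinations of stage and chromosomes. In Purkinje-like, granule neuron-like and unipolar brush cell-like cells this call held in all 27 alternatives. In granule progenitor-like and radial glia and astroglia-like cells it was lost in 7 and 8 of 16 fits with a library left out. With all cells summed Mid1 was higher by 0.67 ± 0.121 (adjusted p = 0.0716), and it was not called by chromosomes (-0.08, adjusted p = 1).

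Ptgds, the prostaglandin D synthase gene, which meninges and choroid plexus express strongly, was higher with testes by 3.45 ± 0.448 (SE) in Purkinje-like cells, at 14.5 ± 7.63 against 1.16 ± 0.847 CPM (SD, n = 8, edgeR adjusted p = 0.00372), and by 2.38 ± 0.269 in granule progenitor-like cells, at 12.7 ± 6.17 against 2.48 ± 0.502 CPM. The difference was 3.81 in mural-like, 1.54 in radial glia and astroglia-like, 1.52 in granule neuron-like and 0.75 in unipolar brush cell-like cells. In the first pair of classes this call held in all alternatives, and in mural-like, radial glia and astroglia-like and granule neuron-like cells it was lost in 3, 9 and 4 of 16 fits with a library left out, in unipolar brush cell-like cells without E18.5 XY testes replicate 2 (0.61, adjusted p = 0.051), and in mural-like cells also with doublets kept (2.77, adjusted p = 0.107). Ptgds moved with markers of other cells: in Purkinje-like cells all 5 tested meningeal fibroblast genes were higher with testes when adjusted over the list alone, with 0 called over all genes, Dcn at 1.42 and Col1a2 at 1.32.

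**Figure D3:**
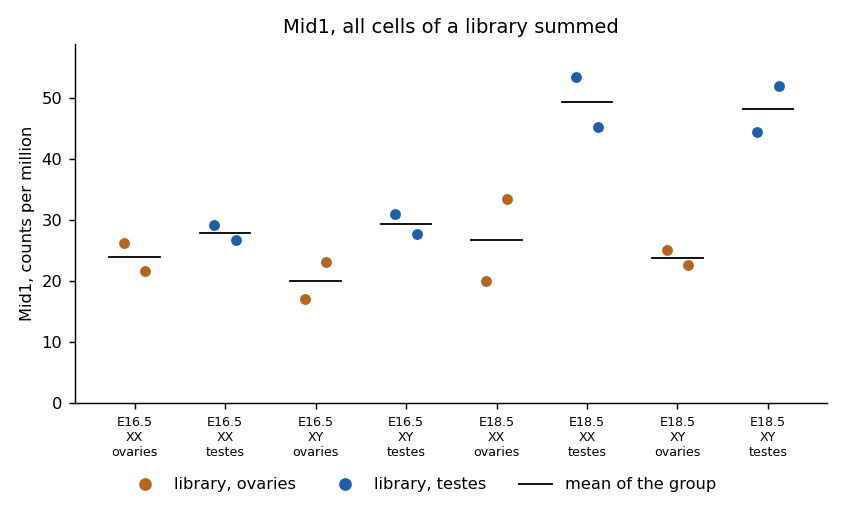
CPM of Mid1 in each library, with all analysed cells summed, for the 8 groups of 2 libraries. Points are libraries coloured by gonads and lines are group means. At E18.5 the 4 libraries with testes lie at 44.4 to 53.5 CPM, and E18.5 XX ovaries replicate 3 lies at 33.4 CPM.

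Unipolar brush cell-like cells, a class of excitatory interneurons, held most calls for gonads with all 16 libraries, 388 genes higher and 540 lower with testes, but without E18.5 XX ovaries replicate 3 granule neuron-like cells held more (2747 against 2518), and at Leiden resolution 0.8 the 928 calls of this class became 435. Of its cells 53.45% with ovaries and 60.79% with testes lay in the larger of its 2 clusters. Taf1d, a cofactor of ribosomal RNA transcription, was higher by 0.51 ± 0.066 (SE), the splicing regulator gene Tra2b by 0.35 and the corepressor gene Rcor2 by 0.38. H3f3a, which encodes histone H3.3, was lower by -0.28 ± 0.039, the kinesin gene Kif5c by -0.43 and Map1b, a gene of axonal microtubules, by -0.38 (1297 ± 122 against 1692 ± 166 CPM, n = 8, edgeR adjusted p = 0.0021). These calls held in all alternatives, except that of Rcor2 at Leiden resolution 0.8. In granule neuron-like cells 24 genes were higher and 18 lower, among them Tra2b at 0.32, which held in all alternatives, Hist1h2ap at 1.68, Rabac1 at -0.21, the mitochondrial gene Chchd2 at -0.24 and H3f3a at -0.20. The calls of the last 4 were lost in 1, 6, 10 and 11 alternatives with a library left out, and that of Hist1h2ap also in the DESeq2 test (1.12, adjusted p = 0.0502). In granule progenitor-like cells the third called gene was Isg20, an interferon-induced exonuclease gene, at 2.51 and at 0.409 ± 0.150 against 0.0724 ± 0.0285 CPM, a call lost with doublets kept (1.30, adjusted p = 0.223). Mural-like cells had Ssrp1 at 0.47, a call lost in 12 of 16 fits with a library left out. Radial glia and astroglia-like cells had Rpp38 at 0.44, Aqp4 at -0.52 and B3gat1 at -0.44, each lost in 8 or more alternatives.

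Over the 9 classes, edgeR called 989 gene-and-class pairs for gonads, 424 higher and 565 lower with testes. In all cells summed it called 0 genes, with 5757 at an unadjusted p under 0.05, and DESeq2 called 2506. It also called 0 in GABAergic interneuron lineage-like, erythroid-like and ventricular zone GABAergic progenitor-like cells, with 1307, 495 and 1417 at an unadjusted p under 0.05 and with 5, 22 and 117 calls by DESeq2. The count rested on single libraries. It was 10744 without E18.5 XX ovaries replicate 3, 220 without E18.5 XX ovaries replicate 2, 261 and 550 without replicates 3 and 2 of E18.5 XY ovaries, 263 and 294 without replicates 2 and 3 of E18.5 XY testes, 541 and 602 without replicates 3 and 2 of E18.5 XX testes, 559 without E16.5 XY testes replicate 2, and 611 without E16.5 XX ovaries replicate 3 and also without E16.5 XY ovaries replicate 3. In unipolar brush cell-like cells alone it ranged from 211 to 2518 between the same 2 libraries of E18.5 XX ovaries. Other classes ranged from 2 without E18.5 XY ovaries replicate 3 to 2747 in granule neuron-like, from 2 to 2156 in granule progenitor-like, from 2 to 1432 in Purkinje-like and from 0 without E16.5 XY ovaries replicate 3 to 1223 in radial glia and astroglia-like cells, each highest without E18.5 XX ovaries replicate 3. In all cells summed it was 4198 without E18.5 XX ovaries replicate 3, 1029 without E16.5 XY testes replicate 3, and 2 without E16.5 XY ovaries replicate 2 or without E18.5 XY testes replicate 3. Without both libraries of E18.5 XX ovaries, an alternative added after the results were seen, the counts were 5722 in classes and 1715 in all cells.

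**Figure D4:**
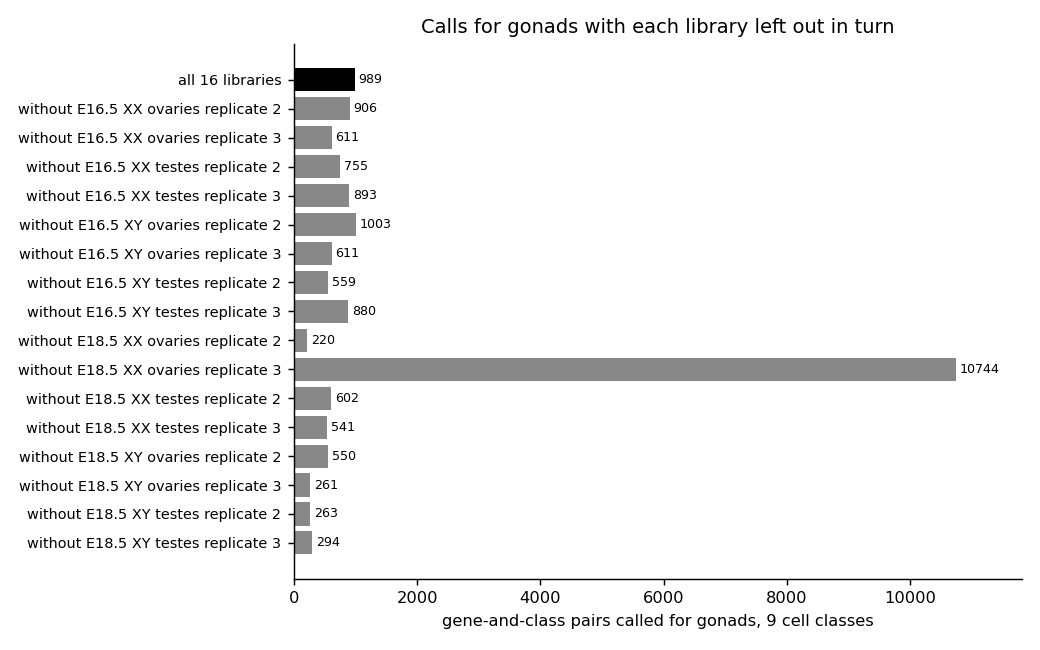
Number of gene-and-class pairs called for gonads over the 9 cell classes, with all 16 libraries (black) and with each library left out in turn (grey). The count of 989 becomes 10744 without E18.5 XX ovaries replicate 3 and 220 without E18.5 XX ovaries replicate 2.

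Lists were tested over both stages together and not within a stage. Egr1 of the immediate early and dissociation stress list, chosen after its values were seen, depended on stage in all cells. At E16.5 it averaged 243.6 CPM with testes and 164.5 CPM with ovaries in XX, and 256.9 and 148.8 CPM in XY. At E18.5 it averaged 159.8 and 151.5 CPM in XX, and 155.3 and 195.5 CPM in XY. As a list, immediate early and dissociation stress genes were higher with testes. In all cells 18 of 28 were higher and 1 lower adjusted over the list alone, with 0 called over all genes, the heat shock genes Hspb1 at 0.90 and Hspa1b at 1.22, Npas4 at -0.42 and Hsp90aa1 at -0.08 (adjusted p = 3.19e-11 by camera and 0.329 with an estimated correlation). Synapse genes were lower: in unipolar brush cell-like cells 11 of 30 were called lower and 15 adjusted over the list alone, and in all cells 23 of 32 adjusted over the list alone and 0 over all genes (adjusted p = 0.329 and 0.452 with an estimated correlation). Gliogenesis genes were lower in 14 of 22 adjusted over the list alone in all cells, with Aqp4 at -0.93, Aldoc at -0.63, Clu at 0.61 and Gja1 at 0.38 (0 called over all genes, adjusted p = 0.484 with an estimated correlation). The shares of radial glia and astroglia-like cells moved the same way: 11.9 ± 2.54% with testes and 14.8 ± 2.73% with ovaries. S phase genes were higher in mural-like cells in 20 of 40 adjusted over the list alone, with Mcm4 at 0.64, Wdr76 at 1.01 and Mcm6 at -0.07. Those of GABAergic interneuron lineage-like cells were lower in 5 of 42 (adjusted p = 0.329 in both with an estimated correlation).

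Lists of other cell types were higher with testes inside the neural classes. Hemoglobin genes had a median of 1.43 in granule progenitor-like cells, Hba-a1 at 1.36 and Hba-a2 at 1.35, 5 of 6 adjusted over the list alone. Of the microglia genes there, C1qb lay at 1.57 and C1qc at 1.46, and 5 of 5 were higher adjusted over the list alone. Choroid plexus genes had one of 0.796 in GABAergic interneuron lineage-like cells, with Folr1 at 1.45, Igf2 at 1.09 and Prlr at -0.67, 4 higher and 1 lower of 8 adjusted over the list alone. All 3 lists had 0 calls over all genes and an adjusted p of 0.329 with an estimated correlation. Mitochondrially encoded genes were higher in erythroid-like cells, 9 of 13 adjusted over the list alone, with mt-Co1 at 0.48 and mt-Atp6 at 0.39 (adjusted p = 0.329 with an estimated correlation), and 3 of 13 were called higher in unipolar brush cell-like cells. With all cells summed, mt-Co1 at E18.5 lay at 1366 to 2038 CPM in the libraries with ovaries and 2558 to 2693 CPM in those with testes, while at E16.5 it lay at 2350 to 2673 and 2584 to 2653 CPM. With this moved a sign of cell quality: barcodes over the mitochondrial limit numbered 265 to 349 in the E18.5 libraries with testes and 48 to 158 in those with ovaries, while at E16.5 they overlapped, with 146 to 235 and 115 to 183. The shares of microglia and macrophage-like cells were 1.57 ± 0.410% with testes and 0.740 ± 0.496% with ovaries, and those of meningeal fibroblast-like cells 5.90 ± 2.72 and 3.23 ± 2.39% (exact permutation test, n = 8, adjusted p = 0.0741 for both). E18.5 XX ovaries replicate 2 stood apart in these cells, with 1 meningeal fibroblast-like, 19 choroid plexus-like and 2 microglia and macrophage-like cells of 7902, and with Ptgds at 14.1 CPM with all cells summed, where the other 7 libraries with ovaries had 70.1 to 164 CPM.

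Further lists passed camera for gonads without a called member in the population where they are named. The X segment reported on the Y of some colonies had a median of 0.476 in all cells, with Mid1 at 0.67, Arhgap6 at 0.50, Tmsb4x at -0.29 and Hccs at 0.00 (fry adjusted p = 0.022, adjusted p = 0.329 with an estimated correlation). The rest lost their call at adjusted p of 0.404 to 0.65 with an estimated correlation: ribosomal protein genes in mural-like cells (Rpl22l1 at 0.42, Rpl35 at 0.47 and Rpl7 at 0.00), oxidative phosphorylation genes in erythroid-like cells (Ndufb2 at 0.38, Ndufa1 at 0.39, Atp5g2 at -0.17 and Atp5o at -0.07), cholesterol synthesis genes in all cells (Fdps at -0.16, Pmvk at -0.15 and Insig1 at 0.11), motile cilium genes in all cells (Drc1 at 0.51, Dnaaf1 at 0.52, Ccdc153 at -0.45 and Tmem212 at -1.27), G2 and M phase genes in erythroid-like cells (Bub1 at -0.63, Hmgb2 at -0.30, Nusap1 at 0.35 and Kif20b at 0.62), midbrain genes in granule progenitor-like cells (En1 at 0.39, Barhl2 at 0.17 and Lmx1b at -0.31), blood vessel genes in all cells (Cdh5 at 0.60, Pdgfrb at 0.35 and Rgs5 at -0.02) and sonic hedgehog targets in mural-like cells (Ccnd1 at 0.51, Ccnd2 at 0.66, Ptch1 at -0.27 and Gli3 at -0.04). In all, 81 of 213 pairs passed camera, 55 up and 26 down, 0 with an estimated correlation (adjusted p = 0.329 to 0.761), and fry called 2.

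The steroid and androgen lists did not differ by gonads. Among 65 androgen response genes in mural-like cells, where their adjusted p was smallest (0.184), the median was 0.061. Among 11 steroid receptor and metabolism genes in ventricular zone GABAergic progenitor-like cells it was -0.045 (adjusted p = 0.147). Notch and progenitor genes, polycomb genes, glycolysis and hypoxia genes, X-inactivation and escape genes and hindbrain Hox genes did not pass camera for gonads either (smallest adjusted p 0.122, 0.266, 0.0923, 0.431 and 0.347). For chromosomes the smallest adjusted p was 0.376 for the steroid list and 0.746 for the androgen list, and for stage 0.364 and 0.315.

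No class share passed the test for gonads: 0 of 16, with 7 at an unadjusted p under 0.05. Ventricular zone GABAergic progenitor-like cells came to 3.02 ± 0.447% with testes and 3.66 ± 0.357% with ovaries (exact permutation test, n = 8, p = 0.00617, adjusted p = 0.0741), and granule neuron-like cells to 14.7 ± 6.66 and 16.9 ± 7.53% (adjusted p = 0.0776). Of the 16 shares 7 passed without E18.5 XX ovaries replicate 3, 5 without E16.5 XY ovaries replicate 2, 5 without E16.5 XY testes replicate 3, and 4 with the replicate number removed.

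The interaction of gonads with stage asks whether testes and ovaries differed in another way at E18.5 than at E16.5. Granule progenitor-like cells held 636 such genes, GABAergic interneuron lineage-like cells 453 and Purkinje-like cells 44. With a library left out these counts ranged from 151 to 1810, from 43 to 1684 and from 5 to 1172, and those of unipolar brush cell-like, radial glia and astroglia-like and granule neuron-like cells, 1, 4 and 0 with all libraries, reached 551, 978 and 890. Each was highest without E18.5 XX ovaries replicate 3 and lowest, in the first 3 classes, without E18.5 XY testes replicate 3, E18.5 XX testes replicate 3 and E16.5 XY ovaries replicate 3. In granule progenitor-like cells Brd2, a chromatin reader gene, was higher with testes at E16.5 (176 ± 9.22 against 145 ± 4.32 CPM, n = 4) and lower at E18.5 (138 ± 5.98 against 169 ± 10.5 CPM), an interaction of -0.57 ± 0.076 (SE, edgeR adjusted p = 0.00327), and Fem1c turned the same way at -0.60. In GABAergic interneuron lineage-like cells Kctd16, which encodes a subunit of GABA-B receptors, was lower with testes at E16.5 and higher at E18.5, at 0.79 ± 0.104 (SE). Gpc5, a glypican gene, in Purkinje-like cells went from 8.85 against 13.5 CPM to 9.34 against 2.81 CPM, at 2.35, and Ncoa4, which serves iron release in red cells, in erythroid-like cells lay at 2.20. Over the classes 591 pairs went up and 592 down. The gonads effect within a stage had 830 calls over the classes at E16.5, 757 of them in granule progenitor-like cells, and 1194 at E18.5, with 552 in unipolar brush cell-like and 336 in GABAergic interneuron lineage-like cells. The count of 1183 became 7295 without E18.5 XX ovaries replicate 3, 260 and 323 without E18.5 XX testes replicate 3 and E16.5 XX testes replicate 2, 274 and 311 without E18.5 XY testes replicate 3 and E16.5 XY ovaries replicate 3, 425 and 496 without E18.5 XY ovaries replicate 2 and E16.5 XX ovaries replicate 3, and 570 and 741 without E16.5 XY testes replicate 2 and E16.5 XX testes replicate 3. In all cells summed edgeR called 0, with 3110 at an unadjusted p under 0.05, and DESeq2 called 641.

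The interaction of gonads with chromosomes asks whether the gonads mattered in another way in XX than in XY animals. It held in 6 gene-and-class pairs. In radial glia and astroglia-like cells Col2a1, a collagen gene, was at 72.4 CPM with testes and 81.6 CPM with ovaries in XX, and at 84.1 and 66.2 CPM in XY (n = 4), an interaction of 0.52 ± 0.081 (SE, edgeR adjusted p = 0.029), and the ephrin receptor gene Epha5 lay at 0.79. Igfbp6 there and the hindbrain patterning genes Hoxa2 and Hoxb2 in granule progenitor-like cells lay at 4.99, 6.64 and 8.92. Their highest means over the 4 libraries of a combination of gonads and chromosomes were 7.38, 1.38 and 3.24 CPM, with SDs of 7.9, 1.5 and 4.0. Leaving out a library gave between 0 and 40 calls: 40 and 0 without replicates 2 and 3 of E16.5 XX ovaries, 35 and 10 without replicates 2 and 3 of E18.5 XX ovaries, 10 and 1 without replicates 2 and 3 of E18.5 XY ovaries, 0 and 3 without replicates 2 and 3 of E18.5 XX testes, 0 without E16.5 XX testes replicate 2, without E16.5 XY ovaries replicate 2 and without E16.5 XY ovaries replicate 3, 2 without E16.5 XY testes replicate 3 and 3 without E18.5 XY testes replicate 2. In all cells summed edgeR and DESeq2 called 0, with 379 at an unadjusted p under 0.05.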

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

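The tests of a wrong gonads label, of a copy carried on the Y chromosome and of free RNA from meningeal fibroblasts were chosen after the results they concern were seen, and the rules for reading the tests of a wrong gonads label and of pseudogene copies were changed after their values were seen, in both cases from excluding the explanation to leaving it open.

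In the following genes the difference between testes and ovaries itself differed between stages, by an interaction term fitted with edgeR. Kctd16, a gene for a GABA-B receptor subunit, in GABAergic interneuron lineage-like cells had an interaction of 0.79 (45.0 against 51.9 CPM at E16.5 and 54.2 against 35.8 CPM at E18.5, testes first). In granule progenitor-like cells the chromatin reader gene Brd2 had one of -0.57 and Fem1c one of -0.60 (38.2 against 29.8 CPM and 33.0 against 39.1 CPM). Gpc5 in Purkinje-like cells had one of 2.35. Ncoa4, an iron release gene, in erythroid-like cells had one of 2.20 (84.4 against 112 CPM and 188 against 47.6 CPM). The call of each of these genes held in all 27 alternatives that were run. Of 30 splits of the libraries, only the real one gave as many calls as 1183, and the highest other gave 33. The other splits were fitted without the interaction term, so a real interaction stays in their spread and lowers their counts. Cell or RNA quality was not tested as a cause of these calls and stays open. With all cells summed, mt-Co1 at E18.5 lay at 1366 to 2038 CPM with ovaries and 2558 to 2693 CPM with testes. At E16.5 its ranges overlapped, at 2350 to 2673 CPM with ovaries and 2584 to 2653 CPM with testes.

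In other genes the difference between testes and ovaries differed between XX and XY animals. In radial glia and astroglia-like cells these were Col2a1 at 0.52, Epha5 at 0.79 (55.1 against 68.3 CPM in XX and 71.5 against 49.3 CPM in XY, testes first) and Igfbp6 at 4.99 (1.23 against 4.61 CPM and 7.38 against 0.835 CPM). In granule progenitor-like cells they were the hindbrain patterning genes Hoxa2 at 6.64 (0.185 against 1.38 CPM and 1.15 against 0.0784 CPM) and Hoxb2 at 8.92 (0.143 against 3.24 CPM and 2.84 against 0.103 CPM). Each of these calls was lost in 8 to 10 of 16 fits with a library left out. Of 30 splits, 5 gave at least the real count of 6, and the highest other gave 12, so chance cannot be excluded.

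The first pattern weighed is the 928 genes called for gonads in unipolar brush cell-like cells, with Map1b, Kif5c and synapse genes lower and Taf1d and Tra2b higher with testes. At Leiden resolution 0.8 there were 435 calls, and 811 to 1340 under the other alternatives that keep all libraries. Free RNA from meningeal, choroid plexus, blood and immune cells is argued against: 1.29% of the called genes were over 5 times higher in those cells, where 3.94% of all tested genes were. Libraries at different points of the course from E16.5 to E18.5 may contribute, since the gonads and stage differences correlated across genes at -0.24, but rearranging the gonads label within stage and chromosomes often gave as strong a correlation (exact two-sided permutation p = 0.332, with genes that are not independent replicates). A wrong gonads label of E18.5 XX ovaries replicate 3 stays open and would hide calls more than make them: there were 2518 without this library and 2603 with it coded as testes. A term for this library alone called 780 genes with its own label and 10 when coded as testes. Such terms for the other 15 libraries called 0 to 4. Their fits kept this library coded as ovaries, which widens the spread, so the 10 cannot be set against them. Its Mid1 (33.4 CPM, all cells summed) lay above the other 3 E18.5 libraries with ovaries (19.95 to 25.02 CPM) and below all with testes (44.4 CPM or more). Other genes, chosen after their values were seen, were compared between both E18.5 XX ovaries libraries and the E18.5 libraries with testes. Isg20 (0.249 to 0.356 against 0.977 to 1.18 CPM) and Gm10076 (274.5 to 286.3 against 472.1 to 648.4 CPM) ran with the label. Aqp4 overlapped (13.58 to 25.78 against 9.478 to 14.17 CPM). At E16.5 Isg20 overlapped between ovaries and testes (0.371 to 0.810 against 0.551 to 0.808 CPM), as did Gm10076 (131.8 to 235.3 against 115.8 to 290.4 CPM). Genes chosen with this library coded as ovaries cannot check its label. A mixed origin stays open too. A difference in the quality of cells or RNA was not tested as a whole and stays open: mt-Co1 at E18.5, all cells summed, lay at 1366 to 2038 CPM with ovaries and 2558 to 2693 CPM with testes, and with cells of at most 5% mitochondrial UMIs there were 887 calls. So does a shift between the 2 clusters of this class, of which the larger held 53.45% of its cells with ovaries and 60.79% with testes. An effect of the gonads also stays open. Of 30 splits only the real one gave as many calls in this class (928, highest other 81), but the class was singled out for its calls, and over all classes another split gave 998.

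The second pattern is Mid1, higher with testes in Purkinje-like, granule neuron-like and unipolar brush cell-like cells in all alternatives. A copy of this gene carried on the Y chromosome is argued against: in the 8 XX libraries alone, which have no Y, Mid1 was higher with testes by 0.63, 0.64 and 0.79 in these classes (lower 95% limits 0.34, 0.24 and 0.23). Counting of genes with named pseudogene copies, of which Mid1 is one, may be part of it and stays undecided: 280 such genes had a median absolute difference by gonads at E18.5 of 0.092, at percentile 44 of 10000 matched random lists, whose median was also 0.092. An effect of the gonads stays open, as does one of the place where the testis-determining gene was inserted, which goes with the gonads in this design. Cell or RNA quality was not tested as a cause and stays open too. With all cells summed, Mid1 at E18.5 averaged 26.68 CPM with ovaries and 49.33 CPM with testes in XX, and 23.79 and 48.21 CPM in XY. At E16.5 these means lay closer, at 23.97 and 27.94 CPM in XX and 20.03 and 29.3 CPM in XY. At E18.5 mt-Co1 also separated by gonads, at 1366 to 2038 CPM with ovaries and 2558 to 2693 CPM with testes.

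The third pattern is Ptgds, higher with testes in 6 classes. Free RNA from meningeal fibroblasts is a candidate explanation: fibroblast-like cells held 1520 CPM of Ptgds, 55.8 to 212 times the level of these classes, and the fibroblast list moved the same way by 0.44 of the difference of Ptgds (median over classes), with 0 list members called by edgeR. Free RNA from choroid plexus could contribute as well, since Ttr rose by 0.45 of that difference and was called in unipolar brush cell-like cells alone (0.94, adjusted p = 0.0373). In every class but unipolar brush cell-like cells Ptgds moved more than either. In Purkinje-like and mural-like cells it lay at 3.45 and 3.81, the fibroblast list had a median of 1.24 and 0.26, and Ttr lay at 0.93 and 1.16. In granule progenitor-like, radial glia and astroglia-like and granule neuron-like cells Ptgds lay at 2.38, 1.54 and 1.52. The list had a median of 0.97, 0.72 and 1.03 there, and Ttr lay at 0.87, 0.94 and 0.82. In unipolar brush cell-like cells both moved more than Ptgds (0.75), with Ttr at 0.94 and the list, there a single gene, at 0.95. Ptgds led the markers of a fibroblast-like cluster of 516 cells, so free Ptgds need not move like the list, and these values do not decide between the sources. Empty droplets are not in the deposited matrices, so a difference inside these cells and free RNA cannot be told apart here.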

How the results depend on the processing

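Leaving out both libraries of E18.5 XX ovaries together was chosen after the results were seen, and every other alternative before the data were examined. For each change given here, the cause was not tested.

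The stage and chromosomes counts moved by less than 1.5 times under the alternatives run, except that without a filter on low counts the chromosomes count in classes was 503, against 95. With a library left out, stage counts ranged from 10948 to 12256 in all cells and from 44743 to 52001 in classes, and chromosomes counts from 14 to 16 and from 89 to 96.

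The gonads counts depended on single libraries. They ranged from 0 to 4198 in all cells and from 220 to 10744 in classes, the interaction with chromosomes from 0 to 40 and that with stage from 260 to 7295. In the same order, the DESeq2 test gave 2506, 2693, 62 and 2339 calls, and leaving out both E18.5 XX ovaries libraries gave 1715, 5722, 10 and 4542. Without a low-count filter the last 3 of these results were 5917, 797 and 3988. At Leiden resolution 0.8 the gonads count in classes was 538.

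With an estimated correlation, list calls went to 0 for gonads, 10 for chromosomes and 0 for stage. Without a low-count filter the chromosomes lists came to 65. With a library left out, list counts ranged from 77 to 88, from 28 to 55 and from 56 to 70. Class shares that differed by gonads ranged from 0 to 7, by chromosomes from 0 to 0 and by stage from 10 to 13. With the replicate number as a block, 4 shares differed by gonads, and the gonads counts were 0 in all cells and 847 in classes. Replicate numbers do not pair the libraries (median r of -0.0381 over 28 pairs of groups).

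No result reversed. Named genes stayed on their side of the threshold in 9757 cases, lost their call in 259 and gained one in 150. Class shares did so in 1025, 5 and 23 cases. Counts per class stayed within 1.5 times in 921 cases and moved further in 294. Among calls named in the report, library totals alone ended those of Cdon, Nfib, Ankrd37 and Ssrp1, keeping doublets those of Nasp, Igfbp6, Isg20, Ssrp1 and Ptgds in mural-like cells, and the DESeq2 test those of Hist1h2ap and Hoxb2. The replicate number as a block ended those of Hoxb2, Rpp38, B3gat1, Ssrp1 and 5530601H04Rik in ventricular zone GABAergic progenitor-like cells. The last of these calls also ended with a block within stage and with a minimum of 2000 UMIs. Leiden resolution 0.8 ended it too, and those of Rcor2, Pbdc1 in granule neuron-like cells and Kdm6a in unipolar brush cell-like cells. Leaving out both E18.5 XX ovaries libraries ended those of Ankrd37, Col2a1, Pbdc1 in granule neuron-like cells, and Kdm6a in Purkinje-like and unipolar brush cell-like cells. In simulated data each gene was drawn on its own. There, calls recovered 36% of genes changed 1.5-fold in erythroid-like cells, 47% in mural-like cells and 65 to 81% in the other populations. The first pair held the fewest UMIs per library, but all cells summed, the deepest, recovered 65%, so depth alone does not set these shares.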

Other observations

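The comparison of the split with 692 calls with the labels was chosen after its result was seen, and no other test in this part.

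Other splits of the 16 libraries into 8 and 8 were counted for each number of calls. For stage, only the real split gave as many calls. In all cells it gave 11681, over 100 splits (1 split as large, highest other 1). In classes it gave 48091, over 30 splits (1 split as large, highest other 57). Each other split took the place of the tested term, so the stage difference stayed in its spread and lowered its count. The low counts of the other splits were thus largely set in advance and cannot exclude chance. This limit holds for each contrast with a real difference. For chromosomes, 1 split of 30 gave as many as 95 calls in classes (highest other 14). In all cells 2 of 100 splits gave as many as 15, and the other of these gave 692. That is many times the real count and points to a structure of the libraries. This split follows the interaction of gonads with stage in 14 of the 16 libraries, with E16.5 ovaries and E18.5 testes on 1 side, except E16.5 XY ovaries replicate 3 and E18.5 XX ovaries replicate 3.

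For gonads, 2 of 30 splits gave as many calls in classes as 989 (highest other 998), so chance is not excluded for this count. The calls of the other split lay mainly in granule neuron-like cells, where the highest other split gave 899 and the real one 42. In all cells the real count was 0, so all 100 splits were as large (highest other 2). For gene lists, 1 split of 30 gave as many as 81 for gonads (highest other 76), 30 of 30 as many as 35 for chromosomes (highest other 69) and 6 of 30 as many as 60 for stage (highest other 73). The medians over the other splits were 53, 57 and 52. For chromosomes and stage, chance is not excluded for these counts. For gonads only the real split reached its count.

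By a chi-square on counts, the 2 libraries of E18.5 XX ovaries differed most from each other, at 269.9 per degree of freedom over 18597 genes. The next group, E16.5 XY testes, had 169.7 and the closest, E16.5 XX ovaries, 35.15. Abundant genes weigh most in this measure. Ttr, for example, lay at 2734 and 39800 CPM in the libraries of E18.5 XX ovaries and at 58100 and 88350 CPM in those of E16.5 XY testes. The order of the groups therefore does not show how many genes differed.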
